A study of Mus musculus with 6 samples.

How the data were processed

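The series holds 6 samples of embryonic mouse forebrain culture, 3 labelled VPA and 3 labelled control, each hybridised to 1 array. Per the labels' protocols, total RNA was extracted with a column kit, its quality was checked on a Bioanalyzer, and 100 ng were amplified and labelled with Cy3 by a whole-transcript kit. Groups were taken from the treatment named in the sample titles, and replicate numbers from the same titles.

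Per the file headers, the deposited intensity values were made with Agilent Feature Extraction 11.5.1.1 under a 1-colour protocol, which subtracts the background and corrects spatial trends within each array. They were not normalized between arrays. The authors' deposited value table holds log2 values, and how it was made is not given in the sources used here. Set against the scanner values of the same array, each of its columns correlated at 1 with log2 of the processed signal minus the array's 75th percentile, without centring per probe. The medians of its columns lay between -1.9 and -1.85. It holds 233398 of the 235712 probes, and 2314 are not in it. It served as an alternative.

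Each array carries 420288 spots, of which 411345 are not controls. Control spots and spots flagged as outliers (176 to 388 per array) were left out, and spots of the same probe were averaged. The main values were log2 of the processed signal minus the 75th percentile of each array. A probe counted as well above background on an array where at least 50% of its spots did, and it was kept for gene values where it was so on all 3 arrays of at least 1 group, which left 190372 probes. A gene value was the mean over the kept probes. Accessions on the array were named through a RefSeq gene table of another genome build (GRCm38) than that in the file headers (mm9), so no coordinates are given. In this way 209455 probes received 1 of 21520 symbols, and 26257 probes stayed under their own accession or name. The gene lists hold 908 symbols, of which 887 were measured.

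Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05) on 31105 genes, 19490 of them with a symbol, with a median of 6 kept probes per symbol. The 38 lists, each with at least 5 measured genes, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. Unequal probe changes were tested with diffSplice (F test) on genes with at least 3 probes above background on all 6 arrays. Where a gene was not well above background on any array of a group, the fold is a lower bound for the main values. It sets the mean of the brighter group against a floor. On each array the floor is the higher of the probe's own signal and the lowest signal among probes well above background. Such a bound is no limit for other settings, and some of those gave smaller folds. For within-slide values of a list, its median was placed among the medians of 10000 random lists whose genes lay within 200 ranks of the members' mean level. Their genes were drawn separately, so the percentile does not allow for correlation between members or for variation between arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

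Slide and scan session followed each other. Slide 1 held both groups and slides 2 and 3 held 1 group each, so slide was fitted as a fixed block, as a random block (consensus correlation 0.179) and through the difference within slide 1. The labels give same-numbered samples the same culture number, and their deviations from the group means correlated at 0.432, 0.285 and 0.506 for numbers 1 to 3, against at most 0.0223 with another number. The numbers were therefore taken to pair the samples. The fit without the block was kept as the main one, as set in advance, and blocked values stand beside it where they change a call.

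Before the data were examined, the groups, the tests, the lists, the other settings to be tried and the rule for named genes were fixed. The rule takes 16 genes of interneurons, Notch signalling and histone deacetylation whatever their result, the 12 largest rises and 12 largest falls past the threshold with the same direction in all pairs and at least 2 kept probes, up to 4 passing members of each list, and the 6 genes with the smallest p for unequal probes. Only 7 falls met it. Of the 39 symbols past the threshold, 1 is not reported here by name and was left out of the values of single genes under other settings. Genes that the same list rule picks from the blocked fit were added after the values were seen. The normexp background correction (offset 50), planned on the mean spot signal, was run on the median spot signal and median local background instead.

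Each test was checked on simulated arrays with the real means and shrunken spreads. For the gene test on 31105 genes, 10% of genes changed by 0.5 on the log2 scale were recovered, 78% of those changed by 1, 92% of those changed by 2 and all of those changed by 4, with 7 unchanged genes called beside 200 changed ones and 0 genes called when none changed. For lists, 10 of 10 lists shifted by 0.2 and 0 of 10 unshifted lists were called. For unequal probes on 14792 genes, 92% of genes with 1 in 3 probes changed by 1 were recovered, but 60 unchanged genes were called as well, and 18 genes were called when none changed, or 46 with unshrunken spreads, so the count of 444 includes some false calls. The check had at first required few false calls of this test as well, which the test did not meet with unshrunken or shrunken spreads. The requirement was then kept for the gene test alone, and the test of probes was used as set in advance, with this error rate. The values read within slide 1 for genes picked from cultures 2 and 3 alone were added after the results were seen, because genes picked with slide 1 in the fit favour agreement with it. The filter on dim probes still used all 6 arrays, slide 1 among them. Simulated probes and genes vary independently, which real ones do not.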

Results

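Total RNA from 6 cultures of embryonic mouse forebrain was measured on 1-colour Agilent exon arrays, which carry several probes for most genes. In 3 cultures the labels give treatment with valproic acid (VPA), an antiepileptic drug that inhibits histone deacetylases, and in 3 they give control. The series was made to find which genes VPA changes in an in vitro stand-in for exposure before birth, and its sample descriptions also name alternative splicing. The dose and duration of VPA are not given in the sources used here. Each VPA sample shares a culture number with 1 control sample, so that the arrays form 3 numbered pairs.

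Between 80.6% and 84.8% of the 235712 probes were well above background on each array, and no probe was saturated. The 75th percentile of the signal lay between 415 and 495. Expression over all genes correlated at 0.983 to 0.994 between arrays. The first principal component held 35.7% of the variance and separated the cultures, and the second held 33% and separated VPA from control. The 2 arrays of culture 1 shared slide 1, whereas control replicates 2 and 3 lay on slide 2 and VPA replicates 2 and 3 on slide 3. The median local background was 53 and 57 on slide 2 and 30 to 34 on the other arrays. Slide and group therefore cannot be told apart in cultures 2 and 3, and the difference within culture 1 is given as the within-slide value. With 3 arrays per group, the number of arrays limits the precision.

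The first comparison asked which genes differed between VPA and control cultures. Hox genes, which specify position along the body axis, were among the genes with the largest rises after VPA. Values are log2 differences, VPA minus control, ± the standard error from limma with 3 arrays per group. This error is that of the fit without a block, also for genes that passed only with the block. Hoxd8 rose by 3.36 ± 0.11 (adjusted p = 6.75e-05), Hoxb13 by 3.47 ± 0.17 (adjusted p = 0.000597), Hoxc10 by 2.69 ± 0.22, Hoxd4 by 2.60 ± 0.21 and Hoxc8 by 1.78 ± 0.17. A gene counted as above background where any of its kept probes was. The sizes of Hoxd8, Hoxc10, Hoxd4 and Hoxc8 rest on probes that were dim in controls, so they are not exact. Others, measured by a single probe each, were not well above background on any control array, so that only bounds could be given. For the main values, Hoxd9 was at least 19.6-fold higher and Hoxc9 at least 10.1-fold higher after VPA. The values with normexp and without the filter, given below, fell under these bounds. Hoxc4, also on a single probe, rose by 4.95 ± 0.26 and was above background on 1 of the 3 control arrays, so this size is not exact. The calls of Hoxc10 and Hoxd4 were lost without VPA replicate 1 (adjusted p = 0.0733 and 0.0783) or VPA replicate 2 (0.0698 and 0.0881), and that of Hoxc8 without control replicate 2 or any 1 of the VPA arrays (adjusted p of 0.0763 to 0.149), while the differences stayed between 1.70 and 2.65. The sizes depend on how dim probes are treated. With normexp background correction, whose offset shrinks differences at dim probes, they were 1.15 for Hoxd8, 2.09 for Hoxb13, 0.73 for Hoxc10, 0.68 for Hoxd4, 0.39 for Hoxc8 (adjusted p = 0.122), 1.41 for Hoxd9, 1.01 for Hoxc9 and 2.29 for Hoxc4. Over probes above background on all arrays the calls of Hoxd8 (0.45, adjusted p = 0.243), Hoxd4 (0.23, adjusted p = 0.74), Hoxc10 (-0.22, adjusted p = 0.558) and Hoxc8 (-0.02, adjusted p = 0.956) were lost. Without a filter on dim probes Hoxd9 was at 2.74, and the calls of Hoxd4 (2.02, adjusted p = 0.0612), Hoxc9 (1.51, adjusted p = 0.0612), Hoxc8 (1.45, adjusted p = 0.111) and Hoxc4 (1.72, adjusted p = 0.308) were lost. The brightest probe gave 0.45 for Hoxd8 and 5.94 for Hoxd4.

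Single homeobox genes outside the Hox clusters and the T-box gene Tbx3 rose as well. Vax2, a regulator of ventral eye development, rose by 3.41 ± 0.16 (adjusted p = 0.000597). Barx1, known from stomach and tooth development, rose by 3.01 ± 0.17, and Hmx1, which acts in the developing eye and ear, by 1.70 ± 0.16. En2, which patterns the midbrain and cerebellum, rose by 1.99 ± 0.20, and Tbx3, a T-box repressor of limb and heart development, by 2.01 ± 0.18. Twist1, a basic helix-loop-helix factor of mesenchyme, was at least 12.2-fold higher, and the forkhead gene Foxd1 at least 3.39-fold higher. Fn1, which encodes the matrix protein fibronectin, rose by 1.98 ± 0.10 over 46 probes (adjusted p = 0.000739). Tfap2c, an AP-2 transcription factor, rose by 1.05 ± 0.13, and Adcyap1, which encodes the neuropeptide PACAP, by 0.90 ± 0.08. Outside the rule for named genes and chosen after their values were seen, Onecut3 was at least 39.2-fold higher, Foxd2 at least 6.87-fold and the retinal ganglion cell factor Pou4f2 at least 4.30-fold, each on a single probe. The bounds in this paragraph hold for the main values alone, and normexp gave a smaller fold for each of these genes. For Onecut3 the bound lies close to the plain ratio of 41.3. Onecut2, of the same family as Onecut3 and also named after its value was seen, rose by 1.35 ± 0.11. Without VPA replicate 2 the adjusted p was 0.0881 for Twist1 and Tbx3, 0.148 for En2, Hmx1 and Adcyap1, 0.307 for Foxd1, 0.316 for Tfap2c, 0.118 for Foxd2, 0.271 for Pou4f2 and 0.0644 for Onecut2, and the calls of these genes were lost without 1 or more of the other arrays too, at adjusted p of 0.0529 to 0.229. With normexp Vax2 was at 1.39, Barx1 at 1.57, En2 at 1.22, Tbx3 at 0.61, Twist1 at 1.14, Fn1 at 1.22 and Onecut3 at 2.13, and the calls of Foxd1 (0.49, adjusted p = 0.146), Tfap2c (0.39, adjusted p = 0.0929), Foxd2 (0.58, adjusted p = 0.062) and Pou4f2 (0.50, adjusted p = 0.122) were lost. Over probes above background on all arrays Vax2 was at 1.45, and the calls of Tbx3 (0.45, adjusted p = 0.351) and Tfap2c (0.68, adjusted p = 0.12) were lost. Without the filter those of En2 (adjusted p = 0.0612), Tbx3 (0.111), Tfap2c (0.251) and Pou4f2 (1.44, adjusted p = 0.112) were lost, and Onecut3 was at 2.57. With the median over probes Adcyap1 was at 0.49 (adjusted p = 0.215), Tfap2c at 0.69 (adjusted p = 0.281) and Tbx3 at 1.88 (adjusted p = 0.108), whereas the brightest probe gave 1.45 for Vax2, 3.10 for Hmx1, 1.49 for Adcyap1 and 1.90 for Tfap2c.

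**Figure D1:**
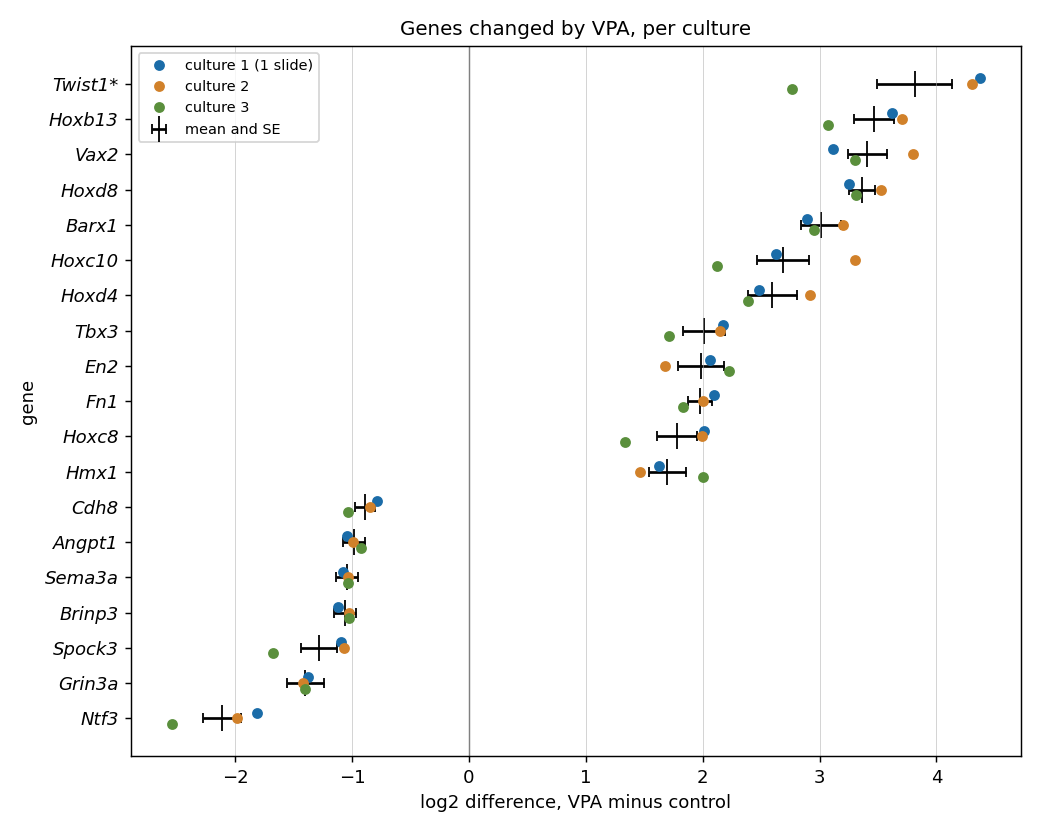
Log2 differences (horizontal axis, VPA minus control) of the 12 genes with the largest rises and the 7 with falls, among genes with at least 2 probes past the threshold. Points are the 3 cultures, and the black mark and bar give the mean and its standard error from limma. The asterisk marks Twist1, which was not well above background in controls, so that its points have no exact size. Those of Hoxd8, Hoxc10, Hoxd4, Hoxc8 and Tbx3 are not exact either, since they rest on probes dim in controls. All points of a gene lie on the same side of 0, as the rule for these genes required, down to -2.54 for Ntf3 in culture 3.

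Of the genes that fell, 7 had a symbol. Ntf3, which encodes the neurotrophin NT-3, fell by 2.11 ± 0.16 on the log2 scale (adjusted p = 0.00767). Grin3a, an NMDA receptor subunit, fell by 1.40 ± 0.16, and Spock3, a secreted proteoglycan, fell by 1.28 ± 0.15. Brinp3 fell by 1.06 ± 0.09, and the axon repellent Sema3a fell by 1.05 ± 0.09. Angpt1, a ligand of the endothelial receptor Tie2, fell by 0.99 ± 0.10, and the cadherin Cdh8 fell by 0.89 ± 0.09. Each of these 7 genes fell in all 3 cultures, with culture 1 values from -1.81 for Ntf3 to -0.78 for Cdh8. The call of Ntf3 was lost without control replicate 2 alone, and each of the other 6 was lost without control replicate 2, VPA replicate 1, 2 or 3. Without control replicate 2, Ntf3 was at -2.09 (adjusted p = 0.0555), and without VPA replicate 2, which moved the others most, their adjusted p was 0.148 for Brinp3, Sema3a and Angpt1, 0.154 for Cdh8, 0.195 for Grin3a and 0.295 for Spock3. With normexp Ntf3 was at -1.29, Brinp3 at -0.60, Sema3a at -0.61 and Angpt1 at -0.53. The calls of Grin3a and Spock3 were lost without the filter (adjusted p = 0.082 and 0.0991) and with probes above background on all arrays (0.0574 and 0.0696), with their sizes kept.

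In all, 42 of 31105 genes passed limma's test at an adjusted p under 0.05, of which 34 were higher and 8 lower after VPA, and 3207 genes had an unadjusted p under 0.05. All 42 differed in the same direction in all 3 cultures, and the VPA and control values did not overlap in 15.7% of all genes, against 10% by chance. Their median size was 1.73 within slide 1 and 1.70 in cultures 2 and 3. With the culture number as a block, 305 genes passed (193 higher and 112 lower), including all 42, and all 305 had the same direction within slide 1. Culture 1 was in both fits that picked these genes, so the choice itself favours this agreement, which is no separate support. With slide as a fixed block, where only the pair of culture 1 informs the difference, limma called 0 genes, with a smallest adjusted p of 0.0669 and 753 genes at an unadjusted p under 0.05, while slide as a random block left 32 genes. From cultures 2 and 3 alone, 9 genes passed as higher, among them Hoxd9, Hoxc9, Hoxc4, Hoxd8, Hoxb13, Vax2, Fn1 and Onecut3, and their median was 3.55 there and 3.62 within slide 1. The 13 genes that passed as lower from those cultures, none with a symbol and none among the 42, had a median of -1.73 there and 0.01 within slide 1. Slide 1 was left out of this fit but not of the filter on dim probes. The balance of rises and falls depends on the arrays used, since without control replicate 1 it turned round, with 833 genes of which 89 were higher and 744 lower. In that fit, as in the one without VPA replicate 1, no slide held both groups. Slide and group therefore cannot be told apart there. Leaving out another array gave 16 genes without control replicate 2 (16 higher and 0 lower), 41 without control replicate 3 (32 and 9), 13 without VPA replicate 1 (12 and 1), 11 without VPA replicate 2 (10 and 1) and 17 without VPA replicate 3 (16 and 1). Hoxd8, Hoxb13, Hoxd9, Hoxc9, Hoxc4, Vax2, Barx1, Fn1 and Onecut3 were the 9 of 38 symbols followed through these fits that passed in each of these 6 fits. The brightest probe of Hoxc8 (-0.02), Hoxc10 (-0.22) and Tbx3 (-0.35) was not higher after VPA, so that the probes of these genes disagree.

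The title of the series points to interneurons that express Vip, and Vip and other interneuron genes had lower values after VPA, but none of those on the fixed interneuron lists passed without a block. Vip, a peptide of caudal ganglionic eminence (CGE) interneurons, differed by -2.37 ± 0.54, with -2.66, -1.82 and -2.62 in cultures 1 to 3. Of its 7 probes, 6 lay between -3.02 and -1.55, but the brightest was at -0.78 (adjusted p = 0.189 as the gene's value), and with normexp background correction Vip was at -1.15 (adjusted p = 0.199). It did not pass limma's test without a block (adjusted p = 0.264) and passed with the culture number as a block (standard error 0.18, adjusted p = 0.0139). The other markers fixed for this class were Calb2, the calcium-binding protein calretinin, at -0.37 ± 0.30 (-0.01 without VPA replicate 3), and the serotonin receptor gene Htr3a at -0.27 ± 0.11 (-0.10 with normexp), and neither passed in either fit. The 2 GABA-synthesising enzymes were at -0.90 ± 0.15 for Gad2 (adjusted p = 0.117, and 0.0234 with the block) and at -0.52 ± 0.14 for Gad1 (adjusted p = 0.364), which also missed the threshold with the block.

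Genes of the interneuron lists that passed only with the block were picked by the rule used for the lists, applied to the blocked fit after its values were seen. From the CGE list they included Ndnf and Lamp5 of neurogliaform cells, at -1.50 ± 0.20 and -1.25 ± 0.58, and Reln, which encodes the secreted guidance protein reelin, at -1.28 ± 0.32. From the list of medial ganglionic eminence (MGE) interneurons they were the peptide genes Sst at -1.34 ± 0.20, Npy at -0.86 ± 0.33 and Tac1, which went the other way at 1.81 ± 0.32. These errors are from the fit without the block. With the block they were 0.10 for Ndnf, 0.12 for Lamp5, 0.14 for Reln, 0.087 for Sst, 0.10 for Npy and 0.22 for Tac1. Adjusted p in limma with the block was 0.0125 for Ndnf, 0.0211 for Lamp5, 0.0262 for Reln, 0.011 for Sst, 0.0374 for Npy and 0.038 for Tac1, against 0.0662 to 0.501 without it. Within slide 1 the differences were -1.40 for Ndnf, -1.24 for Lamp5, -1.07 for Reln, -1.29 for Sst, -0.75 for Npy and 1.54 for Tac1. Smaller values were found for Ndnf with normexp (-0.87), for Lamp5 with normexp (-0.47), without control replicate 1 (-0.80) or without VPA replicate 3 (-0.75), and for Npy without control replicate 3 (-0.49). With the block 6 members of the CGE list fell and 2 rose. The 2 that rose, outside the rule, were Sp8 at 1.17 ± 0.23 and Egfr at 0.51 ± 0.08 (limma adjusted p with the block = 0.0457 and 0.0369).

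**Figure D2:**
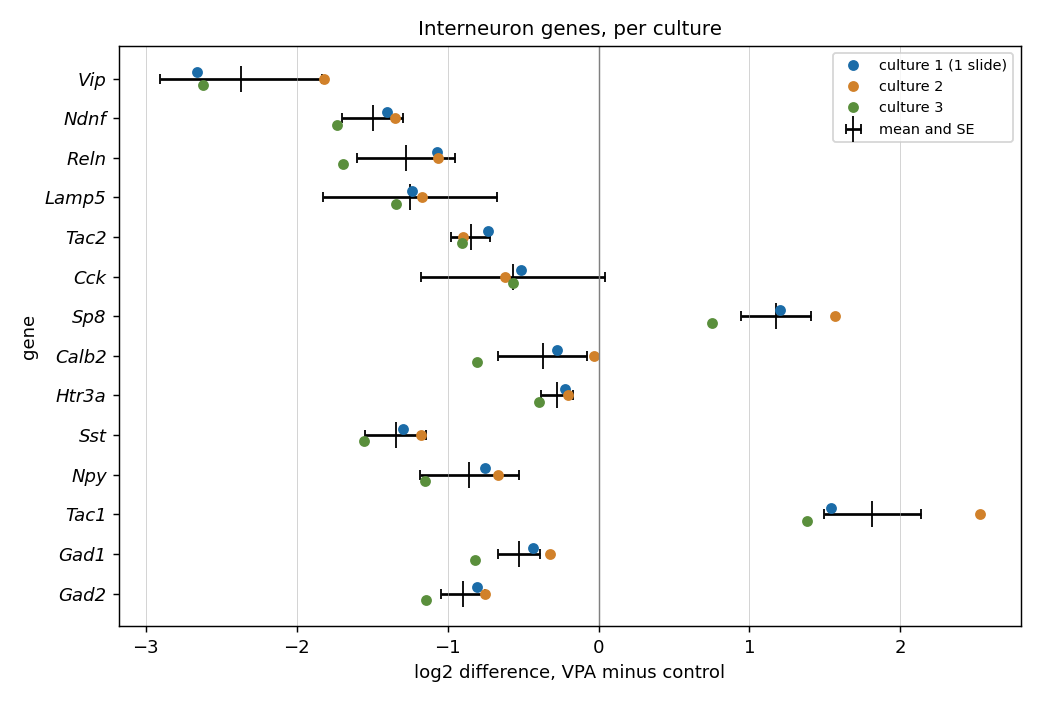
Log2 differences (horizontal axis, VPA minus control) of 14 interneuron and GABAergic genes. These follow no fixed rule, and Egfr of the CGE list, which was higher after VPA, is not drawn. Points are the 3 cultures, and the black mark and bar give the mean and its standard error from limma without a block. Vip lies between -2.66 and -1.82, and Tac1 and Sp8 lie above 0 in every culture.

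The genes fixed in advance for the Notch pathway and for histone deacetylases, which the title also names, did not pass the threshold. Hes5, a Notch target of progenitor cells, was at 0.50 ± 0.28, with 0.10, 0.23 and 1.18 in cultures 1 to 3. Hes1, another target, was at -0.13 ± 0.10. The receptor gene Notch1 was at 0.26 ± 0.11, and the ligand genes Dll1 and Jag1 were at 0.13 ± 0.09 and 0.05 ± 0.12. Hdac1, Hdac2 and Hdac3 were at 0.08 ± 0.08, 0.13 ± 0.13 and -0.03 ± 0.08. Genes often raised by histone deacetylase inhibitors were at 0.24 ± 0.11 for Cdkn1a, a cell cycle inhibitor, and 0.12 ± 0.12 for the linker histone gene H1f0, and the neurotrophin gene Bdnf was at -0.31 ± 0.32. None of these 11 genes passed limma's test without or with the block. The 95% interval of Hes5 ran from -0.16 to 1.16. On simulated arrays the test recovered 10% of genes changed by 0.5, so differences of that size are not excluded.

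The second comparison asked whether gene lists fixed in advance shifted as a whole. Of 38 lists, 14 passed limma's camera test with a preset correlation of 0.01 between genes, 8 upward and 6 downward, and 19 passed with the culture number as a block, 13 of them shared. Other splits of the 6 arrays into groups of 3 gave 9 to 16 lists without a block. The count of 14 is therefore no larger than such groupings give. With an estimated correlation 0 lists passed (3 at an unadjusted p under 0.05), the smallest adjusted p being 0.216, and fry called 1 list, that of Hox genes. With slide as a fixed block 16 lists passed, of which 5 were among the 14: the Hox, proneural, neuropeptide, presynaptic and CGE lists. When this fit was given an estimated correlation 0 of the 38 passed, the smallest adjusted p being 0.577. The other 9 of the 14 were lost there, and the adjusted p of each is given with its list. Counts of members follow the test over all genes, then the test adjusted over the list alone.

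The list of Hox and posterior identity genes moved up. Of 26 measured members 7 rose, 0 fell and 19 did not pass, and 11 rose and 1 fell when adjusted over the list alone. Its median was 0.07, its mean 1.09 and its median within slide 1 0.27, above 99.99% of 10000 random lists matched on level (camera adjusted p = 1.04e-08, adjusted p = 0.216 with an estimated correlation). The largest rises were those of Hoxd9, Hoxc4, Hoxc9 and Hoxd8. With probes above background on all arrays the list was not called (median -0.0047, adjusted p = 0.456), its median was 0.11 with quantile normalization and 0.18 without the filter, and on the brightest probe it was called at a median of -0.013. Proneural and intermediate progenitor genes, active in cells about to become neurons, had a median of 0.27, with 1 of 19 members rising, Tfap2c, and 5 when adjusted over the list alone (camera adjusted p = 2.59e-05, adjusted p = 0.216 with an estimated correlation). Members that passed only with the block were Igfbpl1 at 1.15 ± 0.21, the zinc finger gene Insm1 at 0.91 ± 0.18 and the RNA-binding protein gene Elavl4 at 0.42 ± 0.11, and the list's median was 0.16 within slide 1, above 99.95% of matched lists, and 0.14 with normexp.

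Forebrain patterning genes had a median of 0.14 over 33 members, with 0.18, 0.22 and 0.0078 in cultures 1 to 3 (camera adjusted p = 0.00155, adjusted p = 0.505 with an estimated correlation). None of the members passed over all genes and 1 rose when adjusted over the list alone. Zic2, a zinc finger factor of the dorsal midline, passed only with the block, at 0.58 ± 0.15. Radial glia and neural progenitor genes had a median of 0.12 with 0 of 25 members past the threshold (1 adjusted over the list alone), and 0.03 within slide 1, at the 62.9th percentile of matched lists (camera adjusted p = 0.00757, adjusted p = 0.714 with an estimated correlation). Wnt pathway genes had a median of 0.08 over 30 members, 0 past the threshold and 5 rising when adjusted over the list alone (camera adjusted p = 0.0125, adjusted p = 0.505 with an estimated correlation). Among them the Wnt effector Lef1 and the receptor gene Fzd9 passed only with the block, at 1.11 ± 0.18 and 0.64 ± 0.11, but the value of Lef1 rests on few probes: it was 0.24 with normexp, 0.35 with the median over probes, 0.19 with probes above background on all arrays and -0.43 on the brightest probe. Without control replicate 3 the calls of radial glia and neural progenitor genes (adjusted p = 0.539) and of Wnt pathway genes (adjusted p = 0.111) were lost. On the brightest probe the median was -0.06 for forebrain patterning genes (adjusted p = 0.0964) and -0.05 for Wnt pathway genes, whose camera direction turned (adjusted p = 0.915), and with normexp it was 0.06 for forebrain patterning genes. The fit with slide as a fixed block gave an adjusted p of 0.0622 for forebrain patterning genes, 0.898 for radial glia and neural progenitor genes and 0.123 for Wnt pathway genes.

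Small upward shifts were called for 3 lists in which 0 members passed, also when adjusted over the list alone. The 31 Notch pathway components had a median of 0.05 (camera adjusted p = 0.0125, adjusted p = 0.386 with an estimated correlation). The 27 histone deacetylase genes had a median of 0.08 (camera adjusted p = 0.0125, adjusted p = 0.505 with an estimated correlation), and the 25 histone acetyltransferase and methyltransferase genes had a median of 0.07 (camera adjusted p = 0.0114, adjusted p = 0.749 with an estimated correlation). Within slide 1 the medians were 0.05, 0.0095 and 0.016, at the 76.4th, 33.3rd and 46.6th percentiles of matched lists, and with slide as a fixed block the adjusted p was 0.844, 0.966 and 0.966 and the camera direction of the latter 2 lists turned downward. Without control replicate 3 the adjusted p of Notch pathway components was 0.135 and that of histone deacetylase genes 0.0765, and without control replicate 2 it was 0.0505 for histone deacetylase genes and 0.0501 for histone acetyltransferase and methyltransferase genes, whose adjusted p was 0.136 without VPA replicate 3. On the brightest probe the calls of these last 2 lists were lost (adjusted p = 0.392 and 0.0568), and the median of Notch pathway components was 0.08 there and with the median over probes.

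Neuropeptide and granin genes had a median of -0.37 over 27 members, and -0.18 within slide 1, below all of 10000 matched lists (camera adjusted p = 0.000488, adjusted p = 0.681 with an estimated correlation). Over all genes 1 member rose, Adcyap1, and 0 fell, whereas 2 rose and 8 fell when adjusted over the list alone, and 2 rose and 7 fell with the block. Beyond Vip, Sst and Npy, the gene of neurotensin, Nts, was at -1.33 ± 0.17 (-0.68 with normexp and -0.53 on the brightest probe). CGE-derived interneuron genes had a median of -0.29 over 21 members and -0.22 within slide 1, below all matched lists (camera adjusted p = 0.0125, adjusted p = 0.505 with an estimated correlation). In that list 0 members passed over all genes, 2 rose and 6 fell when adjusted over the list alone, and 2 rose and 6 fell with the block. Presynaptic genes had a median of -0.15 over 29 members, 1 of which fell when adjusted over the list alone, and -0.19 within slide 1, below all matched lists (camera adjusted p = 0.00778, adjusted p = 0.749 with an estimated correlation). MGE-derived interneuron genes had a median of -0.23 over 21 members and -0.25 within slide 1 (camera adjusted p = 0.0548, 0.0228 with the culture block and 0.00453 with slide as a fixed block, and with an estimated correlation 0.793 with the culture block and 0.719 with the slide block). Of these 0 passed over all genes, and 1 rose and 1 fell when adjusted over the list alone. Without control replicate 1 the camera adjusted p was 0.0705 for the neuropeptide list, 0.329 for the CGE list and 0.585 for the presynaptic list, and without VPA replicate 3 it was 0.118 for the CGE list and 0.095 for the presynaptic list. The presynaptic call was also lost on the brightest probe (adjusted p = 0.0895), and with normexp the CGE median was -0.13.

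Markers of other cell types that such cultures can hold were lower as well, mainly in the cultures whose arrays lay on different slides. Microglia and macrophage genes had a median of -0.21 over 22 members, 0 past the threshold and 1 falling when adjusted over the list alone (camera adjusted p = 0.00155, adjusted p = 0.505 with an estimated correlation). Their medians were -0.0052, -0.26 and -0.34 in cultures 1 to 3. Endothelial and pericyte genes had a median of -0.16 over 23 members, 0 past the threshold (camera adjusted p = 0.00778, adjusted p = 0.622 with an estimated correlation), with -0.0097, -0.22 and -0.28 in the 3 cultures. Slco1c1, a thyroid hormone transporter of brain endothelium, passed only with the block, at -0.68 ± 0.20 (-0.42 on the brightest probe). Genes of dopaminergic, cholinergic and other transmitter neurons had a median of -0.17 over 23 members, 0 past the threshold and 1 falling when adjusted over the list alone (camera adjusted p = 0.0356, adjusted p = 0.749 with an estimated correlation), and 0.0021 within slide 1. That last call was lost with the block (camera adjusted p = 0.0603), and without control replicate 1 (0.0705), control replicate 3 (0.0729) or VPA replicate 3 (0.311), and with normexp (0.0503), without the filter (0.112) or with the median over probes (0.0513). The endothelial call was lost without the filter (0.0607), and with normexp the medians were -0.07 for microglial, -0.04 for endothelial and -0.07 for transmitter neuron genes. The within-slide medians of the 3 lists lay at the 28.5th, 21.7th and 27.8th percentiles of matched lists, and with slide as a fixed block their adjusted p was 0.0509, 0.193 and 0.84.

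**Figure D3:**
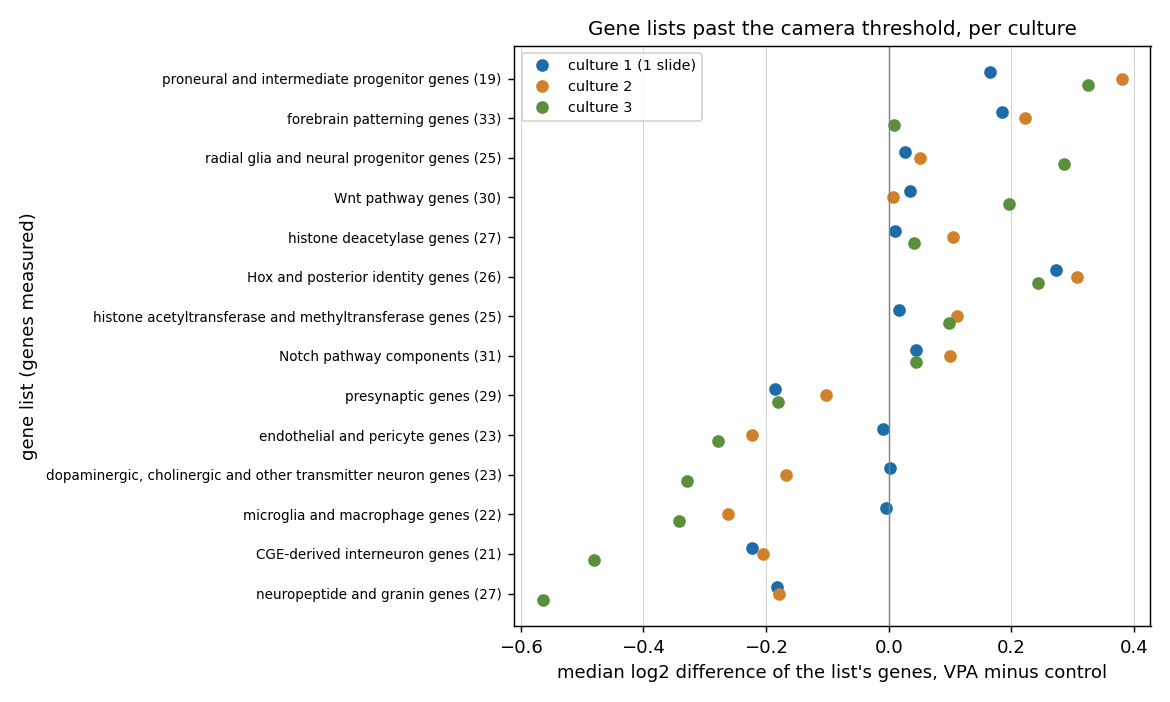
Median log2 difference (horizontal axis, VPA minus control) of the 14 lists past the camera threshold, with the number of genes measured in brackets. Each point is 1 culture, and the arrays of culture 1 shared a slide. In culture 1 the microglial, endothelial and transmitter neuron lists lie at -0.0052, -0.0097 and 0.0021, and the CGE list at -0.22.

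The other lists did not pass without a block. Those called by camera only with the culture number as a block, besides the MGE list, were oligodendrocyte lineage genes with a median of -0.16 (adjusted p = 0.0279 with the block), astrocyte genes with 0.12 (0.0372), cell cycle and DNA replication genes with -0.13 (0.0494), cholesterol biosynthesis genes with -0.16 (0.0494) and postsynaptic and receptor genes with -0.10 (0.0494), and with the block and an estimated correlation the adjusted p of these lists was 0.778, 0.778, 0.924, 0.901 and 0.901. Within slide 1 cell cycle and cholesterol biosynthesis genes were lower by more, at -0.28 and -0.37, but in culture 3 their medians were 0.12 and 0.20. Oligodendrocyte and postsynaptic genes were at -0.19 and -0.10 within slide 1, whereas astrocyte genes went the other way there, at -0.04, the 4.85th percentile of matched lists. With slide as a fixed block the adjusted p of the 5 lists was 0.0163 for oligodendrocyte, 0.966 for astrocyte, 4.8e-11 for cell cycle, 1.66e-08 for cholesterol biosynthesis and 0.00554 for postsynaptic genes, and the same fit called the meningeal and fibroblast list upward (0.00554) and the neurotrophin (0.023), neuronal migration (0.0263) and GABAergic identity (0.0314) lists downward. These calls rest on 1 pair and were lost when that fit was given an estimated correlation, with adjusted p from 0.719 for the cell cycle, cholesterol biosynthesis, meningeal and neurotrophin lists to 0.722 for the neuronal migration, 0.754 for the oligodendrocyte, 0.783 for the GABAergic identity and 0.826 for the postsynaptic list. In these 5 lists 0 members passed over all genes, and 1 cell cycle gene fell when adjusted over the list alone. Meningeal and fibroblast genes had a median of -0.06 but a mean of 0.36 and an upward camera direction (adjusted p = 0.0728), since 3 of 24 members rose, Twist1, Foxd1 and Fn1 (5 rose and 1 fell adjusted over the list alone). In the list of neurotrophin and growth factor signalling genes, with a median of -0.06, Ntf3 fell (2 fell adjusted over the list alone). Among neuronal migration and axon guidance genes, with a median of -0.0075, Sema3a fell (4 fell adjusted over the list alone), and Efna5 at -1.09 ± 0.18 and Nrp1 at 0.78 ± 0.25, a ligand and a receptor in axon guidance, passed only with the block (-0.58 for Efna5 with normexp and 0.51 for Nrp1 without control replicate 3). GABAergic neuron identity had a median of -0.17 (0 passed over all genes and 1 fell adjusted over the list alone), with -0.19, 0.07 and -0.43 in cultures 1 to 3. Pan-neuronal genes had a median of 0.06 (0 in both). Glutamatergic projection neuron genes had a median of 0.05, with Fezf2, a factor of deep-layer cortical neurons, at 1.31 ± 0.19 (0.83 within slide 1) and Neurod1 at -0.76 ± 0.16, both past the threshold only with the block (4 rose and 2 fell adjusted over the list alone).

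Medians were 0.02 for Notch target genes, -0.0035 for HDAC inhibitor marker genes, 0.012 for cell cycle inhibitor and p53 target genes, -0.02 for autism-associated genes and -0.05 for immediate early genes, whose mean was -0.02. They were -0.05 for voltage-gated ion channel genes, 0.04 for ER stress and heat shock genes, -0.07 for fatty acid oxidation and PPAR target genes and -0.09 for interferon response genes. Choroid plexus and ependymal genes were at -0.03, erythroid genes at -0.08 and germline and testis genes at -0.11. The camera direction was upward against a negative median for immediate early, HDAC inhibitor marker, choroid plexus and erythroid genes, and the mean of erythroid genes was 0.08. None of the members of these 12 lists passed over all genes without the block, and adjusted over the list alone 2 erythroid genes, 1 immediate early gene and 1 HDAC inhibitor marker gene rose and 1 voltage-gated ion channel gene fell. Adjusted p of the 12 lists lay between 0.157 and 0.803. In the fit with slide as a fixed block 2 of them were called downward, autism-associated genes (adjusted p = 0.00942, median -0.06 within slide 1) and Notch target genes (adjusted p = 0.0314, median -0.09), both of which missed the threshold when that fit was given an estimated correlation (adjusted p = 0.719).

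The third comparison asked whether probes of the same gene changed unequally, as a change in transcript form would make them. Fn1 stood first: its 45 probes all moved up, between 0.05 and 2.89. The gene for the proprotein convertase Pcsk5 split into 23 probes that were higher, up to 0.83, and 12 that were lower, down to -0.35, with an adjusted p of 0.389 for the gene as a whole. In Wt1, a zinc finger factor of kidney and gonad, 2 of 8 probes were higher by 3.36 and 3.35, 1 by 0.59, and 5 lay between -0.49 and -0.18. Lsr, which encodes a tricellular junction receptor, had probes at 2.86, 2.39 and 0.70 and 4 others between -0.27 and -0.05. In Lef1 a single probe was at 2.89 and the others lay between -0.58 and 0.17. Sdk2, an adhesion gene of the retina, had 45 probes between -0.48 and 0.81. Within slide 1 the lower probes were not all lower: 8 of the 12 in Pcsk5 were above 0 there, as were 3 of 5 in Wt1, 3 of 4 in Lsr, 1 of 4 in Lef1 and 5 of 8 in Sdk2. Some of the lower probes were far brighter than the rest. In Pcsk5 they reached control levels of 4.25 to 4.71, while its higher probes lay at 1.27 or below. In Wt1 a probe at -0.19 had a control level of 6.31. In Fn1, whose probes all moved up, brighter probes tended to change less (correlation of change with control level -0.705, and -0.800 in Sdk2). The Fn1 probe at 0.05 had a control level of 0.13 and that at 2.89 one of -4.20. Its brightest probe, at a control level of 1.45, went the other way and moved by 2.38. Whether such probes read these genes was not tested. Which exon each of these probes reads is not analysed here.

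Of 14792 genes with at least 3 probes above background on all arrays, 444 passed limma's diffSplice F test at an adjusted p under 0.05 and 1798 had an unadjusted p under 0.05. Adjusted p was 2.46e-50 for Fn1, 1.95e-15 for Pcsk5, 3.71e-15 for Wt1, 1.25e-12 for Sdk2, 6.79e-10 for Lsr and 9.9e-10 for Lef1. With the culture number as a block 1482 genes passed, 407 of them shared, and all 6 named genes were among them. With slide as a fixed block 22 passed, 6 of them shared, and Fn1, Wt1 and Lef1 remained past the threshold (adjusted p = 1.83e-13, 3.98e-05 and 0.00371), whereas Pcsk5, Sdk2 and Lsr did not. Leaving out 1 array gave 79 genes without VPA replicate 2 to 2496 without control replicate 1, with 82 and 175 without control replicates 2 and 3 and 182 and 201 without VPA replicates 1 and 3. Without an array of culture 1 no slide held both groups. From cultures 2 and 3 alone 1903 genes passed, all 6 named genes among them (adjusted p of 5.41e-25 for Fn1 to 2.32e-05 for Lsr). Within these 1903 genes the probe changes of slide 1 correlated with those of cultures 2 and 3 at a median of 0.157 across probes, against 0.0926 in the other genes. Over the 444 genes, which were chosen with slide 1 in the fit, the median of this correlation was 0.615. In the 6 named genes, chosen from that same fit, it was 0.704 for Sdk2 to 0.995 for Lsr. The choice favours agreement with slide 1 in both cases.

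**Figure D4:**
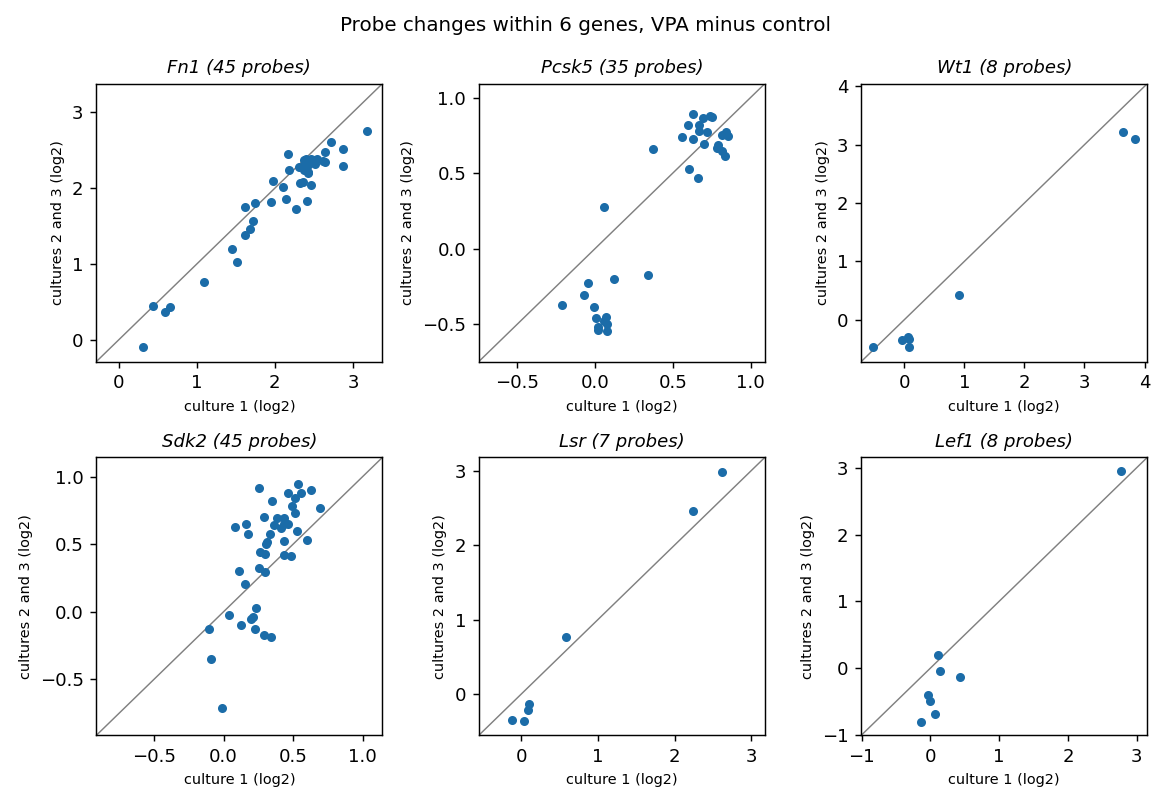
Probe changes within the 6 genes with the smallest p for unequal probe changes. Each point is 1 probe, with its log2 difference (VPA minus control) in culture 1 on the horizontal axis and the mean of cultures 2 and 3 on the vertical axis, and the line marks equal values. In Wt1, Lsr and Lef1 probes at up to 3.36, 2.86 and 2.89 on average stand apart from probes near 0.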

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

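The tests that leave out both arrays of a culture, the test of symbols alone, and the slide block with an estimated correlation, were chosen after the data were seen. With 3 arrays per group, and with slide following group in cultures 2 and 3, the counts moved far. The 42 changed genes became 44 with normexp background correction, 48 with quantile normalization, 56 with median scaling and 49 with the authors' value table, and 30 of 38 symbols passed in each of these. They became 22 without a filter on dim probes, 18 with probes above background on all arrays and 218 probes when each probe was tested alone. Array weights gave 12137 genes (4759 higher and 7378 lower), with weights of 5.71 and 5.49 for the arrays of culture 2 and 0.299 to 0.82 for the others, so that this fit rests almost on 1 pair. The replicate block gave 305 genes, slide as a fixed block 0 and, leaving out an array or a culture, 5 (without culture 2) to 833. The replicate block made 29 of the 81 named genes pass in addition and ended no call among them, and beyond the genes, lists and counts given with it, it changed no other call. For lists, 14 became 0 with an estimated correlation, with or without the slide block, and 1 with fry, and stayed between 11 and 19 otherwise. Camera was not run with slide as a random block, which it does not take. The 444 genes with unequal probes became 713 with normexp, 260 with probes brighter than the median, 920 with the Simes test, 1482 with the replicate block, 22 with slide as a fixed block, 220 with slide as a random block and 12 to 2496 when an array or a culture was left out. The cause of these moves was not tested, except that the slide block leaves 1 pair to inform the difference. Without control replicate 1, which gave the 833 and the 2496, no slide held both groups, so slide and group cannot be told apart.

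Of 1854 alternative values of single genes, 1455 kept direction and side of the threshold, 300 lost the call, 77 gained it and 22 reversed. Of 836 for lists these were 637, 77, 58 and 64. Reversed gene values were, with the brightest probe, -0.21 for Dll1, -0.034 for Jag1, -0.22 for Hoxc10, -0.35 for Tbx3, -0.021 for Hoxc8, -0.43 for Lef1, -0.0029 for Thbs1, -0.19 for Wt1, -0.11 for Lsr, -0.32 for Tmem159 and -0.083 for Skor1. With the median over probes they were -0.023 for Jag1, 0.0032 for Hdac3 and -0.16 for Wt1. With probes above background on all arrays they were -0.22 for Hoxc10 and -0.021 for Hoxc8, with normexp 0.012 for Hes1, and with slide as a fixed block -0.033 for Hdac1 and -0.020 for Hdac2. List directions turned in the camera test at medians of -0.042 (erythroid genes) and -0.0020 (germline and testis genes) with normexp, -0.11 (erythroid genes) without the filter, and -0.063 (Notch target genes) with probes above background on all arrays. With the replicate block they turned at -0.084 (erythroid genes), -0.050 (immediate early genes) and -0.0075 (neuronal migration and axon guidance genes). With slide as a fixed block, under either correlation, they turned for germline and testis genes (0.079), glutamatergic projection neuron genes (-0.022), histone acetyltransferase and methyltransferase genes (0.016), histone deacetylase genes (0.0095), interferon response genes (0.081), Notch target genes (-0.090), pan-neuronal genes (-0.031) and radial glia and neural progenitor genes (0.027). With the brightest probe they turned for cell cycle inhibitor and p53 target genes (-0.14), choroid plexus and ependymal genes (-0.27), erythroid genes (-0.23) and Wnt pathway genes (-0.048), and with fry for HDAC inhibitor marker genes (-0.0035) and Notch target genes (0.022).

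When arrays or cultures were left out, values that turned ranged from -0.011 to 0.096 for Jag1, -0.011 to 0.24 for Hdac2 and -0.066 to 0.019 for Hdac3. The list medians ranged from -0.12 to 0.28 for astrocyte genes, -0.029 to 0.0029 for autism-associated genes, -0.29 to -0.014 for cell cycle and DNA replication genes, -0.34 to 0.0069 for cholesterol biosynthesis genes, -0.16 to 0.015 for erythroid genes and -0.12 to 0.0076 for fatty acid oxidation and PPAR target genes. They ranged from -0.18 to 0.023 for germline and testis genes, -0.12 to 0.16 for glutamatergic projection neuron genes, -0.054 to 0.047 for HDAC inhibitor marker genes, -0.23 to 0.22 for immediate early genes, -0.12 to 0.011 for interferon response genes and -0.078 to 0.027 for neuronal migration and axon guidance genes. They ranged from -0.082 to 0.015 for neurotrophin and growth factor signalling genes, -0.094 to 0.084 for Notch target genes, -0.0029 to 0.11 for pan-neuronal genes, -0.22 to 0.0044 for postsynaptic and receptor genes and -0.14 to -0.0033 for voltage-gated ion channel genes. Of the 14 lists, 5 passed without each array in turn: the Hox, proneural, forebrain patterning, microglial and endothelial lists. The CGE and presynaptic calls were lost without control replicate 1 or VPA replicate 3, and the neuropeptide call without control replicate 1. Calls of the Notch component, radial glia and Wnt lists were lost without control replicate 3, that of the histone deacetylase list without control replicate 2 or 3, that of the acetyltransferase list without control replicate 2 or VPA replicate 3, and that of the transmitter neuron list without control replicate 1 or 3 or VPA replicate 3.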

Other observations

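The tests of gene families, of Hox clusters, of slides, of dim probes and of GABAergic neurons below were chosen after the main results were seen, and those of hindbrain markers, of homeobox genes as a class and of other splits before their own results were seen. Of 25 families, 10 passed camera with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.812). The clustered protocadherins, which give neurons different surface identities, had a median of 0.15 over 53 genes and 0.11 within slide 1, above 99.95% of matched lists (camera adjusted p = 3.39e-09). Serotonin receptor genes had a median of -0.26 over 14 genes and -0.17 within slide 1 (camera adjusted p = 0.0168), with 2 members past the threshold only with the block. Zfp zinc finger genes had a median of 0.04 over 367 genes and 0.06 within slide 1, above 99.99% of matched lists, and keratin genes -0.15 and -0.10. Ribosomal protein genes had a median of 0.11 but 0.0069 within slide 1, and collagen genes -0.14 but 0.0034. Olfactory receptor genes had a median of -0.14 but went the other way within slide 1, at 0.07, the 99.5th percentile of matched lists.

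Among 31 measured Hox genes 8 rose, in 4 of 9 HoxC, 3 of 7 HoxD, 1 of 6 HoxB and 0 of 9 HoxA genes. A hypothesis from this is that the HoxC and HoxD clusters may respond more than HoxA and HoxB. The difference of the medians was 1.31 over all cultures and 1.67 within slide 1, over 16 and 15 genes. These are the genes that prompted the hypothesis, so the values restate it and it stays untested. Hoxb13, on 2 probes, rose outside this pattern. Hoxc13, on a single probe not well above background in controls, was at least 7.90-fold higher for the main values (limma adjusted p = 0.0996, and 0.0234 with the block). A second hypothesis, that homeobox genes outside the Hox clusters rise as a class, was written before its test. Of 154 such genes 9 rose and 0 fell (16 and 0 with the block), and camera called them upward (adjusted p = 0.00399, adjusted p = 0.812 with an estimated correlation), but their median was 0.0092 overall. Within slide 1 it was 0.0584, at the 97.0th percentile of matched lists, and resampling its members gave 0.0161 to 0.129, a range that holds the 0.1 set in advance, so whether the class shifted stays open. This range was added after the median was seen.

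The rise of Hox and other transcription factor genes was seen within slide 1. The 9 genes that rose in cultures 2 and 3 alone had a median of 3.62 there (lowest 2.10). The filter on dim probes used the VPA array of slide 1 too, which favours a rise there for probes dim in controls. For genes that rest on such probes, Hoxd9, Hoxc9, Hoxc4 and Onecut3 among them, the value therefore cannot exclude a difference between slides. Fn1, with 45 of 46 kept probes above background on all arrays, was at 2.10 within slide 1. For this gene that argues against a slide difference. Hindbrain or spinal cord tissue in the VPA cultures would bring its abundant neuronal genes. The 15 markers, 5 of which are also on another list and all above background in controls, had a median of -0.119 (quartiles -0.31 and -0.0052), and the brightest were Tlx3 at -0.27 ± 0.13, Prph at 0.54 ± 0.13 and Lbx1 at -0.02 ± 0.08, with none passing. An effect of the VPA treatment, which the groups name, stays open, and how it would act was not tested.

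The lower values of Vip and other interneuron genes were also seen within slide 1, where the CGE list had a median of -0.222, below all matched lists. This rests on 1 pair of arrays, and the matched lists do not allow for correlation between members. Camera with slide as a fixed block and an estimated correlation called 0 lists. The value therefore does not decide whether a slide difference is the cause. Other fixed lists lay below all matched lists there too, such as cell cycle genes at -0.28 and oligodendrocyte lineage genes at -0.19, so a lower median within slide 1 is not particular to interneuron genes. A lower share of all GABAergic neurons would lower Vip and the genes they share alike. The difference of Vip minus the mean difference of Gad1, Gad2 and Slc32a1 was -2.13, -1.43 and -1.67 in cultures 1 to 3, but -0.497, -0.363 and 0.518 on the brightest probe and -1.08, -0.811 and 0.119 with normexp background correction, while 4 other settings gave -2.57 to -1.17, so the outcome depends on the setting. A lower share of these neurons, fewer cells of the Vip class alone and less Vip per cell all stay open.

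Unequal probe changes called from cultures 2 and 3 alone hardly carried over to slide 1, with a median within-gene correlation of 0.157 (quartiles -0.16 and 0.51) against 0.0926 in the other genes. A slide difference predicts this, but so do false calls of this test and noise in the 1 pair of slide 1. The correlation cannot tell these apart, so how much of the count comes from the slides stays open. A first version of this test gave 0.615 over the 444 genes, but these had been chosen with slide 1 in the fit, and it was replaced after its value was seen. A smaller measured change at dim probes may contribute: the median correlation of the size of the change with the control level was -0.0204 over the 444 genes, with quartiles of -0.31 and 0.31, so the test decides nothing for the whole, while in all 6 named genes it was negative (-0.705 for Fn1, -0.607 for Sdk2, nearest to 0 at -0.036 for Pcsk5), the direction opposite to what this explanation predicts. Changed transcript forms stay open for single genes such as Fn1. Its probe changes in slide 1 correlated with those of cultures 2 and 3 at 0.96. Slide 1 was in the fit that chose this gene, which favours that value. Brighter probes of Fn1 tended to change less, and whether they read Fn1 was not tested.

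The 10 splits of the 6 arrays into groups of 3 are too few for a share under 0.05. The real split gave 42 genes and the highest of the other splits 0, and 1 split, the real one, gave as many. With the block, the real split gave 305 genes and the other 3 that part all pairs gave 0. For lists the real split gave 14 and the other splits 9 to 16, and 5 splits, the real one among them, gave 14 or more. With the block the real split gave 19 and the others that part all pairs 11 to 13. For unequal probes the real split gave 444 and 2 splits gave as many. The other, with VPA replicates 1 and 2 and control replicate 1 against the rest, gave 725. The other 3 splits that keep the arrays of slide 1 together gave 36, 32 and 2. Among splits that part all pairs the real one gave 1482 with the block and the highest other 87.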
